A study of Mus musculus with 20 samples.

How the data were processed

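Messenger RNA was measured in mouse aortas with Affymetrix GeneChip arrays of the mouse genome. Each of the 20 arrays was hybridized with biotin-labelled RNA from a pool of 8 aortas, so a replicate is a pool and not a mouse. The arrays formed 7 groups by the labels: chow controls, rosiglitazone at 3 or 10 mg/kg/day for 2 or 14 days, wild-type littermates and P465L mice. The deposited intensity values were signals per probe set on a linear scale, made by the authors with MAS5, the tool named in the submitters' processing notes. The MAS5 version, the detection calls and any filter were not given in the sources used here. The values themselves showed that each array had been scaled to a mean of 1500 after the lowest and highest 2% of probe sets were set aside, with no other adjustment between arrays. This scaling assumes that the bulk of the signal did not differ between arrays. MAS5 signals of dim probe sets are noisy, which is why an offset and a filter were used below. The ratio of signals from the 3' and 5' ends of transcripts ranged from 0.80 to 0.98 for Gapdh and from 1.17 to 1.35 for Actb.

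Of 45101 probe sets, 64 were array controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. Symbols were checked against a current reference through the Entrez ID, which was found for 34741 probe sets, and 0 symbols changed. Probe sets with 1 symbol covered 18193 genes. Each gene took its probe set with the highest mean over all arrays. Genes were tested if that mean reached the 50th percentile of the means of all probe sets, a log2 value of 8.73 or a signal of 352, which left 11081 genes. Probe sets with several or no symbols were left out of the comparisons because they name no single gene, and were tested apart. Signals were analysed as log2 of the signal plus 72, the 20th percentile of all values. Gene positions were taken from a reference gene table on GRCm38.

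Comparisons were made with limma 3.58.1 in R 4.3.3. A single model with a mean per group was fitted to all 20 arrays, with 13 residual degrees of freedom, and variances were moderated with eBayes along their trend with the mean level, with 7.3 prior degrees of freedom. The number of arrays limits the precision. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were each rosiglitazone group against chow, their average against chow, dose, time, the interaction of dose and time, P465L against wild-type littermates, and wild-type littermates against chow. The same chow controls served all 4 rosiglitazone groups and both times, so the similarity of these groups was set against 50 simulations of groups with no effect that shared the controls. Calls with rosiglitazone and with P465L were set side by side with Fisher's exact test against independent lists, and by a correlation across genes. Array letters showed no pairing common to the groups: over 57 pairs of arrays with the same letter the median r of their deviations from the group means was 0.025. The values ranged from -0.301 to 0.358, so a pairing of some groups is not excluded. No pairing was used in the main fit. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

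Gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The 31 lists were PPAR target genes of lipid handling, adipocyte markers, brown adipocyte markers, fatty acid beta oxidation, peroxisome, fatty acid and triglyceride synthesis, cholesterol synthesis, oxidative phosphorylation, tricarboxylic acid cycle, glucose uptake and glycolysis, smooth muscle contractile genes, endothelial markers, fibroblast and adventitial markers, collagens and collagen processing, elastic fibre and matrix remodelling, vasomotor signalling, antioxidant defence, inflammatory cytokines and adhesion, macrophage markers, lymphocyte markers, interferon response, skeletal muscle markers, cardiac muscle markers, nerve and Schwann cell markers, red blood cell markers, circadian clock, immediate early genes, heat shock and unfolded protein response, cell cycle, sex chromosome genes, and hormone and drug metabolism. Lists overlap, and a gene in several lists counts in each. The adipocyte score of an array is the mean of 16 adipocyte markers outside the PPAR target list. These markers include Pparg itself and genes that PPARγ can regulate.

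The tests, the lists, the thresholds and most of the alternative settings were chosen before the data were examined. So was the rule for named genes. For each rosiglitazone comparison, their average and P465L, it took the 10 genes that rose most and the 10 that fell most among the called genes whose arrays did not overlap between the groups, or, where fewer than 10 genes passed, the 5 smallest unadjusted p-values. For dose, time, the interaction and the untreated groups it took 5 and 5. For rosiglitazone against P465L it took up to 5 genes called in both, and with 1 such gene the same number was taken at the unadjusted threshold. From each list it took up to 3 called members with the largest rise and 3 with the largest fall, or 2 with the smallest unadjusted p if none was called. It always took Pparg, Ppara, Ppard, Rxra, Fabp4, Cd36, Lpl, Plin1, Adipoq, Angptl4, Pdk4, Ucp1, Ucp3, Acta2, Myh11, Nos3, Agt, Rgs5, Retn and Cat. Genes named for another probe set of opposite sign, genes shared by both 10 mg/kg/day groups and liver markers were chosen after their values were seen where the rule did not take them.

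The alternative settings chosen in advance were quantile normalization, no offset, a larger offset of 230 (the 40th percentile), no filter, a stricter filter at the 75th percentile, the mean of the probe sets of a gene, only the arrays of the experiment, eBayes without the trend, array weights, the replicate letter as a block, a fold change of at least 1.5, leaving out each array in turn, and the other list tests. A fit with the adipocyte score as a covariate, leaving out arrays in the list tests and list means, following the direction of all called genes, and the unadjusted threshold for rosiglitazone against P465L were added after seeing the data. The procedure was tested on simulated data with the spread of these arrays, in 5 runs with 200 changed genes each. For P465L it recovered 46.3, 83 and 96.4% of genes changed 1.5-fold, 2-fold and 3-fold, and called 9.6 unchanged genes per run. For rosiglitazone on average it recovered 66.9, 94.9 and 98.5%, with 9.6 unchanged genes called per run. A list shifted as a whole was called in 5 of 5 runs, and 0 lists with no shift were called. The simulated genes varied independently of each other, within a list and outside it, which the genes of the aorta need not do. The recovery rates hold for 200 changed genes per run and may be lower where few genes change.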

Results

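The series measured messenger RNA in the mouse aorta, the artery that carries blood from the heart, after the nuclear receptor PPARγ was activated or interfered with. PPARγ switches on genes of fat storage and lipid handling when fatty acids or drugs bind it. Rosiglitazone, a thiazolidinedione that binds and activates PPARγ, was given in the food to adult C57BL/6J mice at 3 or 10 mg/kg/day for 2 or 14 days, and control mice ate standard chow. In a separate experiment, mice carried a targeted P465L mutation of PPARγ, which the labels describe as dominant negative, and were compared with wild-type littermates. Each of the 20 arrays held RNA pooled from 8 aortas. There were 3 chow controls, 3 arrays in each rosiglitazone group except 10 mg/kg/day for 14 days, which had 2, 3 wild-type littermates and 3 P465L arrays. The number of arrays limits the precision, and the p-values of single genes below measure spread between pools, not between mice. Camera with the preset correlation and Fisher's exact test set genes against other genes, so their p-values do not measure that spread. Every array had a 2% trimmed mean signal of 1500, and the median signal of a probe set ranged from 321.3 to 450.7 between arrays. Pearson's r between replicate arrays, across genes, which are not independent replicates, ranged from 0.964 to 0.988 within the groups. Log2 values below are of the signal plus an offset of 72.

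The first comparison asked how the aorta responded to rosiglitazone on average over its 4 dose and time groups. Acaa1b, an enzyme of fatty acid breakdown in peroxisomes (chromosome 9, 119148043 to 119157093 in GRCm38), rose 3.99-fold as the average of the 4 groups (adjusted p = 0.0197). Its log2 signal was 10.11 ± 0.62 (SD, n = 3) in chow controls and 12.05 ± 0.75 (SD, n = 11) over the treated arrays, where the group of 2 arrays weighs less than in the average of the groups. Rbp7, a retinol-binding protein (chromosome 4, 149449687 to 149466462), rose 3.92-fold (adjusted p = 0.0197). Pdk4, a kinase that shuts pyruvate out of the mitochondrial citric acid cycle, rose 2.71-fold (adjusted p = 0.0305). Angptl4, a secreted inhibitor of lipoprotein lipase, rose 2.39-fold, and Fabp4, the fatty acid carrier of fat cells, rose 1.79-fold, both with an adjusted p of 0.0257. Among the genes that fell, Cyp2f2, a cytochrome P450 enzyme (chromosome 7, 27119955 to 27133660), fell by 1.32 on the log2 scale (SE 0.24, adjusted p = 0.0197), and Pecam1, an adhesion molecule of endothelial cells, fell by 0.57 (SE 0.11, adjusted p = 0.0209).

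In all, limma called 48 of 11081 genes at an adjusted p under 0.05, 26 higher and 22 lower, and 1569 genes had an unadjusted p under 0.05 where 554 were expected by chance. Among called genes whose arrays did not overlap, other rises included those of Cmbl, an esterase-like hydrolase (log2 fold change 1.37), Prkar2b, a regulatory subunit of protein kinase A (1.24), Sgk2, a serine kinase (1.10), Rnd1, a small GTPase (0.95), and Slc40a1, the iron exporter ferroportin (0.94). All 11 rosiglitazone arrays lay above all 3 controls for these genes and the 5 risen genes above, as their selection required. Haghl, which resembles the glyoxalase hydrolases, fell by 0.94, the unfolded protein response enzyme Pdia4 fell by 0.66, and the glutathione transferase Gstt3 fell by 0.62. The microtubule-binding protein Map4 fell by 0.58, the Wnt receptor Fzd2 fell by 0.53, the taurine transporter Slc6a6 fell by 0.52 and the IGF-binding protein Igfbp5 fell by 0.52. Pcid2, a component of messenger RNA export, had a log2 fold change of -0.57 and Bicral, a chromatin remodelling subunit, of -0.52, both called. Btnl9, a butyrophilin-like protein, was called at 1.43 (adjusted p = 0.0179) and Ephx2, the soluble epoxide hydrolase, rose 1.94-fold (adjusted p = 0.0305), although the arrays of the 2 groups overlapped for both, as did those of Cyp2f2. Of 25 called genes with another probe set, 20 moved the same way there, and the log2 fold change there was a median of 0.59 of the reported one. Map3k12, a stress kinase, was called higher at 0.74 but had -0.24 on its other probe set, and Fbxo36, an F-box protein, had 0.78 and -0.28. Ifngr2, a chain of the interferon gamma receptor, was called lower at -0.47 but had 0.74 on its other probe set. With the mean of the probe sets of a gene Map3k12 turned to -0.02 and Ifngr2 to 0.14.

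Pparg itself had a log2 fold change of 0.27 ± 0.31 (SE, adjusted p = 0.757) with rosiglitazone, from a signal of 1197 ± 419 (SD, n = 3) in chow controls. The scavenger receptor and fatty acid transporter Cd36 had 1.07 (adjusted p = 0.0728), the related receptor Ppara had 1.03 (adjusted p = 0.0893), the heat-generating uncoupling protein Ucp1 had 1.38 (adjusted p = 0.107), lipoprotein lipase Lpl had 0.72 (adjusted p = 0.18) and the adipocyte hormone Adipoq had 0.79 (adjusted p = 0.153). None of these passed the test. Ppard (-0.14), Rxra (-0.11), Ucp3 (0.15), Acta2 (0.20), Myh11 (-0.04), Nos3 (-0.23), Rgs5 (0.14), Retn (-0.05) and Cat (0.38) did not pass it either. Agt, the precursor of angiotensin, lay below the level required for testing, with a signal of 27.17 ± 4.92 (SD, n = 3) in chow controls, and Plin1 was not analysed here.

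**Figure D1:**
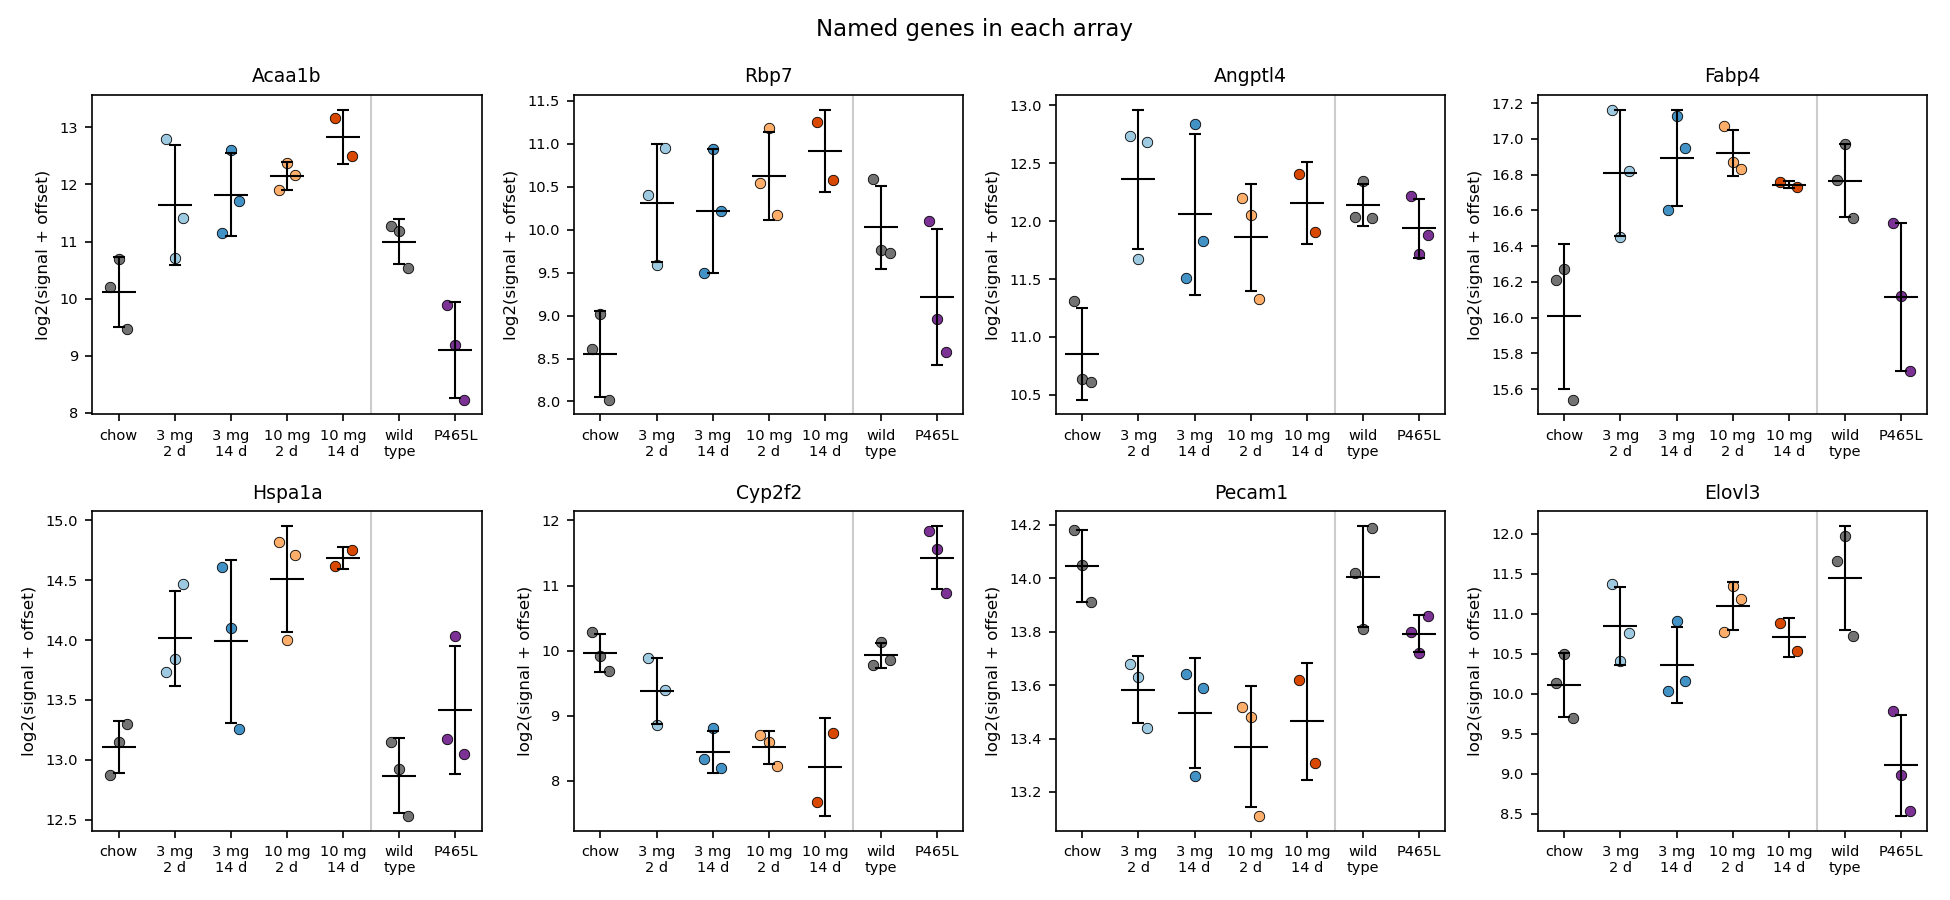
Log2 of signal plus offset (y axis) of 8 genes in each of the 20 arrays, by group (x axis). Points are arrays, horizontal bars are group means and error bars are 1 SD. Acaa1b averaged 10.11 in chow controls and 12.83 at 10 mg/kg/day for 14 days, and Elovl3 averaged 11.45 in wild-type littermates and 9.10 in P465L mice.

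Among the fixed gene lists, the PPAR target genes of lipid handling stood higher in 28 of 31 measured members, with a mean log2 fold change of 0.56. Of these, 5 were called over all genes (Acaa1b, Fabp4, Fabp5, Angptl4 and Pdk4) and 14 higher and 1 lower when adjusted over the list alone. The list rose by camera with a preset correlation of 0.01 (adjusted p = 4.47e-12), with an adjusted p = 0.442 with an estimated correlation. Brown adipocyte markers were higher in 16 of 18 members (mean 0.67, adjusted p = 4.54e-09, and adjusted p = 0.442 with an estimated correlation), with 0 called over all genes and 11 adjusted over the list alone. Fatty acid beta oxidation was higher in 20 of 21 members (mean 0.41, adjusted p = 4.54e-09, and adjusted p = 0.442 with an estimated correlation), with 0 called over all genes and 7 adjusted over the list alone. Oxidative phosphorylation was higher in 57 of 58 (mean 0.25, adjusted p = 5.79e-17, and adjusted p = 0.442 with an estimated correlation), with 1 called either way, the electron carrier cytochrome c, Cycs (0.69). The tricarboxylic acid cycle (22 of 23 higher, adjusted p = 1.46e-07), peroxisome (17 of 22, adjusted p = 2.81e-05) and adipocyte marker (17 of 20, adjusted p = 8.14e-07) lists rose by the same test, each with an adjusted p = 0.442 with an estimated correlation. Adjusted over the list alone, they had 1, 5 and 6 called members, against 0, 1 and 1 over all genes. The adipocyte score, the mean of 16 fat cell markers outside the PPAR target list, moved with them, by 0.36 ± 0.27 (SE) between the same groups. Fatty acid and triglyceride synthesis did not follow: 13 of its 23 members were lower, with a mean of -0.10 (adjusted p = 0.12) and 3 lower members adjusted over the list alone. It was lower with the adipocyte score as a covariate, at a mean of -0.35 (adjusted p = 1.03e-10, and adjusted p = 0.0684 with an estimated correlation), and without chow control C (-0.19, adjusted p = 0.0199) or 10 mg/kg/day 14-day array A (-0.14, adjusted p = 0.0423). Its mean was -0.04 without chow control B, -0.05 without 3 mg/kg/day 2-day array B and -0.06 without 10 mg/kg/day 14-day array B. The adipocyte score holds genes of this list, among them Agpat2, and moved between the same groups. Its use as a covariate is therefore no independent test of this list. With the same covariate the PPAR target list had 0.26, brown adipocyte markers 0.31, beta oxidation 0.14, oxidative phosphorylation 0.09, the tricarboxylic acid cycle 0.07, peroxisome 0.12 and adipocyte markers 0.07, all past the test with the preset correlation. The mean of the 16 markers in the score cannot shift in this fit. The 0.07 of adipocyte markers therefore comes from members shared with the PPAR target list. With the covariate and an estimated correlation none of the 7 passed: the adjusted p was 0.0906 for the first 2 lists, 0.264 for beta oxidation and adipocyte markers, 0.537 for oxidative phosphorylation, 0.61 for the tricarboxylic acid cycle and 0.363 for peroxisome. Without chow control C adipocyte markers had 0.23 in place of 0.44.

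The heat shock and unfolded protein response list was higher in 19 of 24 members (adjusted p = 4.75e-08, and adjusted p = 0.245 with an estimated correlation). The chaperones Hspa1a (2.29-fold) and Hspd1 (1.37-fold), whose arrays overlapped between the groups, and Hspa8 (1.29-fold) rose, while Pdia4 fell. That made 3 higher and 1 lower over all genes, and 11 higher and 1 lower adjusted over the list alone. Immediate early genes, which respond within minutes to stimulation, were higher in 20 of 25 members (adjusted p = 0.000665, and adjusted p = 0.442 with an estimated correlation), with 4 adjusted over the list alone and 0 over all genes. The interferon response was lower in 19 of 21 members (adjusted p = 0.00044) and macrophage markers in 19 of 23 (adjusted p = 0.0128), both with an adjusted p = 0.442 with an estimated correlation. Adjusted over the list alone, 1 interferon gene and 0 macrophage genes were lower, against 0 and 0 over all genes. Without chow control A the macrophage list did not pass (mean -0.06 in place of -0.13, adjusted p = 0.429). Centred over the 20 arrays, the interferon list averaged 0.4, 0.08 and 0.42 in chow controls and -0.47, 0.01 and -0.29 in untreated wild-type littermates. For macrophage markers these values were 0.27, 0.08 and 0.01 against -0.2, 0.03 and -0.04. Chow controls that were high by themselves on these lists are therefore not excluded. Ifit3, an interferon-induced antiviral protein, had -0.51 (adjusted p = 0.0833), and Laptm5, a lysosomal protein of blood cells, had -0.39 (adjusted p = 0.132).

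The other 20 lists did not pass camera in this comparison. The nearest were cholesterol synthesis, fibroblast and adventitial markers, and hormone and drug metabolism, each at an adjusted p of 0.0683. In the last list Cyp2f2 fell and Ephx2 rose, and in the fibroblast list Sfrp4, a secreted Wnt modulator, fell by 0.39 (adjusted p = 0.0305). Lymphocyte markers had 0.108, collagens 0.238, inflammatory cytokines and adhesion 0.256, skeletal muscle 0.34, cell cycle 0.345 and antioxidant defence 0.419 as adjusted p. Glucose uptake and glycolysis and vasomotor signalling had 0.502, endothelial and red blood cell markers 0.698, nerve and Schwann cell markers 0.711, and cardiac muscle 0.788. Smooth muscle contractile genes, elastic fibre and matrix remodelling, the circadian clock and sex chromosome genes each had 0.783. The direction of camera differed from the sign of the mean for smooth muscle (mean -0.02), endothelial markers (0.02), cardiac muscle (-0.07) and the circadian clock (-0.05), and from the sign of the median for elastic fibre (-0.02).

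These counts rested on single arrays: limma called 3, 11 or 1 genes in place of 48 without chow control A, B or C, and 1, 5 or 1 of the 27 named calls stayed. Without 10 mg/kg/day 14-day array A or 3 mg/kg/day 14-day array B it called 28 and 29, and without 3 mg/kg/day 2-day array A or B it called 75 and 83. With array weights, with the adipocyte score as a covariate, without the variance trend and at 1.5-fold or more it called 260, 125, 28 and 25 genes.

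At 10 mg/kg/day for 2 days, limma called 56 genes, 15 higher and 41 lower, and 1687 genes had an unadjusted p under 0.05. Rbp7 rose 4.23-fold, Acaa1b 4.11-fold, Btnl9, a butyrophilin-like membrane protein, 2.78-fold, and the chaperone Hspa1a 2.65-fold. Cyp2f2 fell by 1.45, and Pon1, an enzyme that protects lipoproteins from oxidation, fell by 1.57. H2-Ab1, an MHC class II chain, fell by 1.24 (adjusted p = 0.0235), and Cd74, the invariant chain, fell by 0.89 (adjusted p = 0.0326). Untreated wild-type littermates also stood below the same chow controls, with a log2 fold change of -1.58 for H2-Ab1. Cd74 had log2 values of 12.58, 12.69 and 13 in these littermates and 14.65, 13.79 and 14.36 in chow controls. Coro1a, an actin-binding protein of leukocytes, fell by 0.78, the actin-binding protein Pfn1 fell by 0.88, the leukocyte and endothelial surface protein Cd99 fell by 1.11, and Pecam1 fell by 0.67. The glutathione transferase Gsta3 fell by 1.12, and Haghl fell by 1.23. Necap2 and Spg21, proteins of vesicle traffic, had -0.96 and -0.91, both called. Smaller rises were of Map3k12 and Fbxo36 (both 0.84), Serf1 (0.73), the recombination protein Rad52 (0.72), Tmem186 (0.59) and the antiproliferative gene Tob2 (0.54). Hspd1 (0.53) and Hsp90aa1 (0.52) rose, while Pdia4 (-0.84) and Sfrp4 (-0.48) fell. Map3k12, Fbxo36 and Ifngr2 again had the opposite sign on their other probe sets, and 26 of 33 called genes with another probe set moved the same way there, by a median of 0.36 of the reported log2 fold change.

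The PPAR target list had a mean of 0.46 at 10 mg/kg/day for 2 days, with 24 of 31 members higher (adjusted p = 5.97e-05, and adjusted p = 0.818 with an estimated correlation), 1 called over all genes, and 8 higher and 1 lower adjusted over the list alone. Its mean was 0.27 without chow control C and 0.28 with the adipocyte score as a covariate. The adipocyte score moved by 0.22 ± 0.33 (SE) beside it. Macrophage markers were lower in 20 of 23 members (adjusted p = 0.000768) and the interferon response in 18 of 21 (adjusted p = 0.000172), both with an adjusted p = 0.818 with an estimated correlation. Adjusted over the list alone, 0 macrophage and 4 interferon genes were lower, against 0 and 0 over all genes. The macrophage mean was -0.14 without chow control A, in place of -0.22. As for the average, chow controls that were high by themselves on these lists are not excluded. Heat shock genes were higher in 19 of 24 (adjusted p = 5.97e-05, and adjusted p = 0.815 with an estimated correlation). Without chow control A, B or C the count was 3, 18 or 7, and without treated array A, B or C it was 14, 0 or 11. It was 27 with the mean of the probe sets of a gene, 14 with only the rosiglitazone experiment's arrays, 13 without the variance trend, 612 with array weights and 224 with the adipocyte score as a covariate.

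At 10 mg/kg/day for 14 days, with 2 treated arrays, limma called 30 genes, 13 higher and 17 lower, and 1391 genes had an unadjusted p under 0.05. Acaa1b rose 6.58-fold, Rbp7 5.16-fold, Btnl9 4.08-fold, Hspa1a 2.98-fold and Cmbl 2.87-fold. Ephx2 rose 2.54-fold, Fabp5, the fatty acid carrier of skin and macrophages, 2.39-fold, Rnd1 2.32-fold, Map3k12 1.99-fold and Serf1 1.85-fold. Hspd1 rose by 0.67 on the log2 scale. Cyp2f2 fell by 1.75, Haghl fell by 1.24, Blnk, a linker protein of B cell receptor signalling, fell by 1.15, and the RNA-binding protein Hnrnpl fell by 1.11. Zfp395, a zinc finger protein, fell by 0.99, Gstt3 fell by 0.84, the clathrin adaptor subunit Ap2m1 fell by 0.82, Pfn1 fell by 0.80, Borcs7, a protein of lysosome positioning, fell by 0.73, and Ifngr2 fell by 0.72. The adjusted p of these genes lay between 0.0295 and 0.0454. Ifngr2 (0.61) and Map3k12 (-0.21) had the opposite sign on their other probe sets, and over 11 called genes with another probe set the log2 fold change there was a median of 0.41 of the reported one. The enzyme of fatty acid synthesis Fasn had -1.25 (adjusted p = 0.112) and the desaturase Scd1 had -1.01 (adjusted p = 0.0954), which did not pass.

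The PPAR target list had a mean of 0.64 at this dose and time (24 of 31 higher, adjusted p = 8.42e-09, and adjusted p = 0.463 with an estimated correlation), with 2 called over all genes, and 12 higher and 2 lower adjusted over the list alone. Its mean was 0.36 with the adipocyte score as a covariate. The adipocyte score moved by 0.35 ± 0.37 (SE). It holds genes of fatty acid and triglyceride synthesis, so a fit with it as a covariate is no independent test of that list. Heat shock genes were higher in 18 of 24 members (adjusted p = 8.42e-09, adjusted p = 0.163 with an estimated correlation), and fry, which tests whether the list moves 1 way without comparing it with other genes, gave an adjusted p of 0.0435. Fatty acid and triglyceride synthesis was lower in 15 of 23 members (adjusted p = 0.00428, and adjusted p = 0.537 with an estimated correlation), with 6 lower adjusted over the list alone and 0 over all genes. Its mean of -0.24 was -0.40 without treated array A and -0.49 with the covariate, and without treated array B it was -0.08 and did not pass (adjusted p = 0.175). The count was 0, 3 or 6 without chow control A, B or C, and 1 or 9 without treated array A or B, where the lone treated array was assumed to vary like the other groups. It was 0 with no filter on dim probe sets, 0 without the variance trend, 9 with only the rosiglitazone experiment's arrays, 256 with array weights and 122 with the adipocyte score as a covariate.

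At 3 mg/kg/day limma called 0 genes at 2 days and 0 at 14 days, with 978 and 916 genes at an unadjusted p under 0.05. The genes with the smallest unadjusted p at 2 days did not pass: Cmbl (1.44), Angptl4 (1.51), the collagen gene Col5a3 (0.73), the transporter Mfsd6 (-0.45) and the nuclear protein Aff3 (-0.55) each had an adjusted p of 0.302. At 14 days Pmf1, a kinetochore protein, had 1.12, Fbxo36 0.92 and Cyp2f2 -1.52, each with an adjusted p of 0.19, Cmbl had 1.38 (adjusted p = 0.198), and the glutathione transferase Gstt1 had -0.52 (adjusted p = 0.255). The PPAR target list stood higher in 30 of 31 members at 2 days (mean 0.66, adjusted p = 1.41e-17, and adjusted p = 0.234 with an estimated correlation) and in 26 of 31 at 14 days (mean 0.46, adjusted p = 9.29e-08, and adjusted p = 0.572 with an estimated correlation). Adjusted over the list alone, 13 and 6 members were called higher, against 0 and 0 over all genes. Oxidative phosphorylation was higher in 56 of 58 members at 2 days (mean 0.34, adjusted p = 6.04e-25, and adjusted p = 0.234 with an estimated correlation) and in 56 of 58 at 14 days (mean 0.25, adjusted p = 6.13e-15, and adjusted p = 0.572 with an estimated correlation). At 14 days the PPAR target mean was 0.28 without chow control C and 0.30 without array B, and at 2 days that of oxidative phosphorylation was 0.17 without array A. With the adipocyte score as a covariate the PPAR target means were 0.21 at both times and those of oxidative phosphorylation 0.10 and 0.11. Beside these lists the adipocyte score moved by 0.55 ± 0.33 (SE) at 2 days and by 0.31 ± 0.33 (SE) at 14 days. Without chow control A or 2-day array B the 2-day count was 2 or 3, and without 14-day array C the 14-day count was 5. With the adipocyte score as a covariate the 14-day count was 12.

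The rosiglitazone groups were then compared with each other. Of the 70 genes called in any group, 16 were called at 10 mg/kg/day at both times, 9 higher and 7 lower. The shared higher genes were Acaa1b, Rbp7, Btnl9, Hspa1a, Hspd1, Map3k12, Serf1, Tob2 and the transcriptional coactivator Sub1. The shared lower genes were Cyp2f2, Haghl, Pfn1, Fzd2, Igfbp5, Ifngr2 and Flnc, an actin crosslinker of muscle. The log2 fold changes of these 2 groups correlated across genes at r = 0.692 with a covariance of 0.0527, where simulated groups with no effect that shared the controls gave 0.45 and 0.0182. The other pairs gave r from 0.516 to 0.68 against simulated values from 0.447 to 0.502, and covariances from 0.0324 to 0.0438 against 0.018 to 0.0181. The 3 controls were too few to be parted into independent sets, so the shared controls were not removed from these values. Chow controls that were low by themselves on whole gene lists could raise r in every pair without a drug effect. The simulated values, given without their spread, do not exclude that. Without chow control A, B or C the overlap of 16 was 0, 0 or 1, without 10 mg/kg/day 2-day array A, B or C it was 2, 0 or 4, without 10 mg/kg/day 14-day array A or B it was 0 or 4, and without 3 mg/kg/day 2-day array A it was 25. It was 0 with no filter on dim probe sets or without the variance trend, 7 with the mean of the probe sets of a gene, 6 with only the rosiglitazone experiment's arrays, 147 with array weights and 73 with the adipocyte score as a covariate.

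By limma, dose (10 against 3 mg/kg/day) called 0 genes, with 1405 at an unadjusted p under 0.05 and a smallest adjusted p of 0.133. Time (14 against 2 days) called 0, with 464 and 0.949, and the interaction of dose and time called 0, with 486 and 0.922. Genes of fatty acid and triglyceride synthesis were lower at the higher dose in 21 of 23 members (mean -0.24, adjusted p = 0.000421, and adjusted p = 0.715 with an estimated correlation), with 4 lower adjusted over the list alone and 0 over all genes. Scd1 had -0.65 (adjusted p = 0.21) and Fasn -0.82 (adjusted p = 0.227). Fibroblast and adventitial markers were lower at the higher dose in 21 of 23 members (adjusted p = 0.000421, and adjusted p = 0.667 with an estimated correlation), and 0 were called adjusted over the list alone or over all genes. The adipocyte score differed by -0.15 ± 0.25 (SE) between doses and by -0.05 ± 0.25 (SE) between times. Red blood cell markers were lower at 14 days in 4 of 4 members (mean -0.84, adjusted p = 2.2e-09, and adjusted p = 0.0964 with an estimated correlation), all 4 adjusted over the list alone and 0 over all genes. Elastic fibre genes were lower at 14 days in 25 of 30 members (mean -0.11, adjusted p = 1.02e-05, and adjusted p = 0.152 with an estimated correlation), with 0 called adjusted over the list alone or over all genes. After quantile normalization 2 lists passed for dose in place of 9, without 3 mg/kg/day 2-day array B or 14-day array A 16 or 15 passed, and with only the rosiglitazone experiment's arrays 5 genes were called lower for time. With the adipocyte score as a covariate 11 genes were called for dose and 2 for time. With the replicate letter as a block 2 genes were called for dose. By dose the mean of fatty acid and triglyceride synthesis was -0.14 with the score and -0.16 without 10 mg/kg/day 14-day array B. The score holds genes of that list, so the fit with it is no independent test of the list.

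The second experiment asked what interference with PPARγ did to the aorta. Pparg (chromosome 6, 115360879 to 115490404), the targeted gene, had a signal of 2169 ± 1110 (SD, n = 3) in P465L arrays and 2132 ± 553 (SD, n = 3) in wild-type littermates, a log2 fold change of -0.07 ± 0.39 (SE, adjusted p = 0.981). The mutation changes 1 amino acid and the array measures transcript abundance, so this value does not check the genotype. Elovl3, an enzyme that lengthens fatty acids in brown fat and skin (chromosome 19, 46131897 to 46135694), was 5.08-fold lower in P465L mice, at 9.10 ± 0.63 (SD, n = 3) against 11.45 ± 0.65 (SD, n = 3), with an adjusted p of 0.0087. The stress kinase Map3k12 (chromosome 15, 102497647 to 102517004) was 2.00-fold higher (adjusted p = 0.0327), while its other probe set had a log2 fold change of 0.17. These 2 genes were the only calls by limma, and 823 genes had an unadjusted p under 0.05.

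The next genes by unadjusted p did not pass. Albumin, Alb, a plasma protein made in the liver, had -3.45 ± 0.64 (SE, adjusted p = 0.106), Cyp2f2 had 1.5 ± 0.30 (SE, adjusted p = 0.159) and Rpgrip1, a protein of cilia, had 0.63 ± 0.13 (SE, adjusted p = 0.278). In each, the 3 P465L arrays lay apart from the 3 wild-type arrays. Acaa1b had -1.90 (adjusted p = 0.341), Fabp4 -0.65 (adjusted p = 0.521), Ppara -0.76 (adjusted p = 0.647), Cd36 -0.70 (adjusted p = 0.661) and Ucp1 -1 (adjusted p = 0.663). The endothelial nitric oxide synthase Nos3 had -0.47 (adjusted p = 0.494), and the smooth muscle actin Acta2 had -0.30 (adjusted p = 0.646). Angptl4 (-0.20), Pdk4 (-0.36), Lpl (-0.12), Adipoq (-0.42), Ucp3 (-0.65), Ppard (0.10), Rxra (-0.15), Retn (0.17) and Cat (-0.13) did not pass. Myh11 and Rgs5 had -0.17 and -0.12, and their signs turned after quantile normalization, to 0.05 and 0.03.

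By list, the PPAR target genes were lower in P465L mice in 30 of 31 members, with a mean of -0.49 (adjusted p = 5.26e-10, and adjusted p = 0.389 with an estimated correlation), 0 called over all genes and 1 adjusted over the list alone. Fatty acid beta oxidation was lower in 20 of 21 members (mean -0.50, adjusted p = 5.26e-10) and oxidative phosphorylation in 52 of 58 (mean -0.24, adjusted p = 8e-13), both with an adjusted p = 0.389 with an estimated correlation and with 0 called over all genes or adjusted over the list alone. Brown adipocyte markers were lower in 14 of 18 (mean -0.67, adjusted p = 8.09e-07, and adjusted p = 0.389 with an estimated correlation), with Elovl3 called over all genes and 4 adjusted over the list alone. Without P465L array C the means were -0.29 for the PPAR target list, -0.13 for oxidative phosphorylation and -0.39 for brown adipocyte markers, and without P465L array A that of oxidative phosphorylation was -0.37. With the covariate of the adipocyte score they were -0.25, -0.11 and -0.37, and beta oxidation had -0.28. Beside these lists the adipocyte score moved by -0.30 ± 0.33 (SE). Skeletal muscle markers were lower in 17 of 18 members (mean -0.94, adjusted p = 6.25e-06, and adjusted p = 0.389 with an estimated correlation), with 0 called over all genes or adjusted over the list alone, and their score ranged over all arrays from -1.33 to 2.26. Their mean was -0.43 without wild-type array B, -1.63 without P465L array A and -0.44 without P465L array C. Lymphocyte markers were higher in 11 of 13 (mean 0.40, adjusted p = 0.002) and immediate early genes in 21 of 25 (mean 0.22, adjusted p = 0.000159), both with an adjusted p = 0.389 with an estimated correlation. Adjusted over the list alone they had 0 and 1 called members, against 0 and 0 over all genes. The immunoglobulin chain Ighm had 1.08 (adjusted p = 0.509) and the nuclear receptor Nr4a3 had 0.73 (adjusted p = 0.452). Smooth muscle contractile genes were lower in 20 of 29 members (mean -0.07, adjusted p = 0.00407) and endothelial markers in 18 of 25 (mean -0.13, adjusted p = 0.00423), both with an adjusted p = 0.389 with an estimated correlation and 0 called over all genes or adjusted over the list alone. Without wild-type array A the lymphocyte list did not pass (mean 0.24, adjusted p = 0.0747). Smooth muscle genes did not pass without wild-type array C (adjusted p = 0.0706) or P465L array A (adjusted p = 0.0595), nor endothelial markers without wild-type array C (adjusted p = 0.061). For vasomotor signalling, the interferon response and the circadian clock, whose tests did not pass, the mean and median had opposite signs.

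The count of 2 became 1, 0 and 1 without wild-type array A, B and C, and 3, 0 and 0 without P465L array A, B and C. It was 0 with only the arrays of this experiment. It was 1 after quantile normalization, with the stricter filter or with the mean of the probe sets of a gene. Without the variance trend or with the replicate letter as a block it was also 1. It was 6 with array weights and 7 with the adipocyte score as a covariate.

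**Figure D2:**
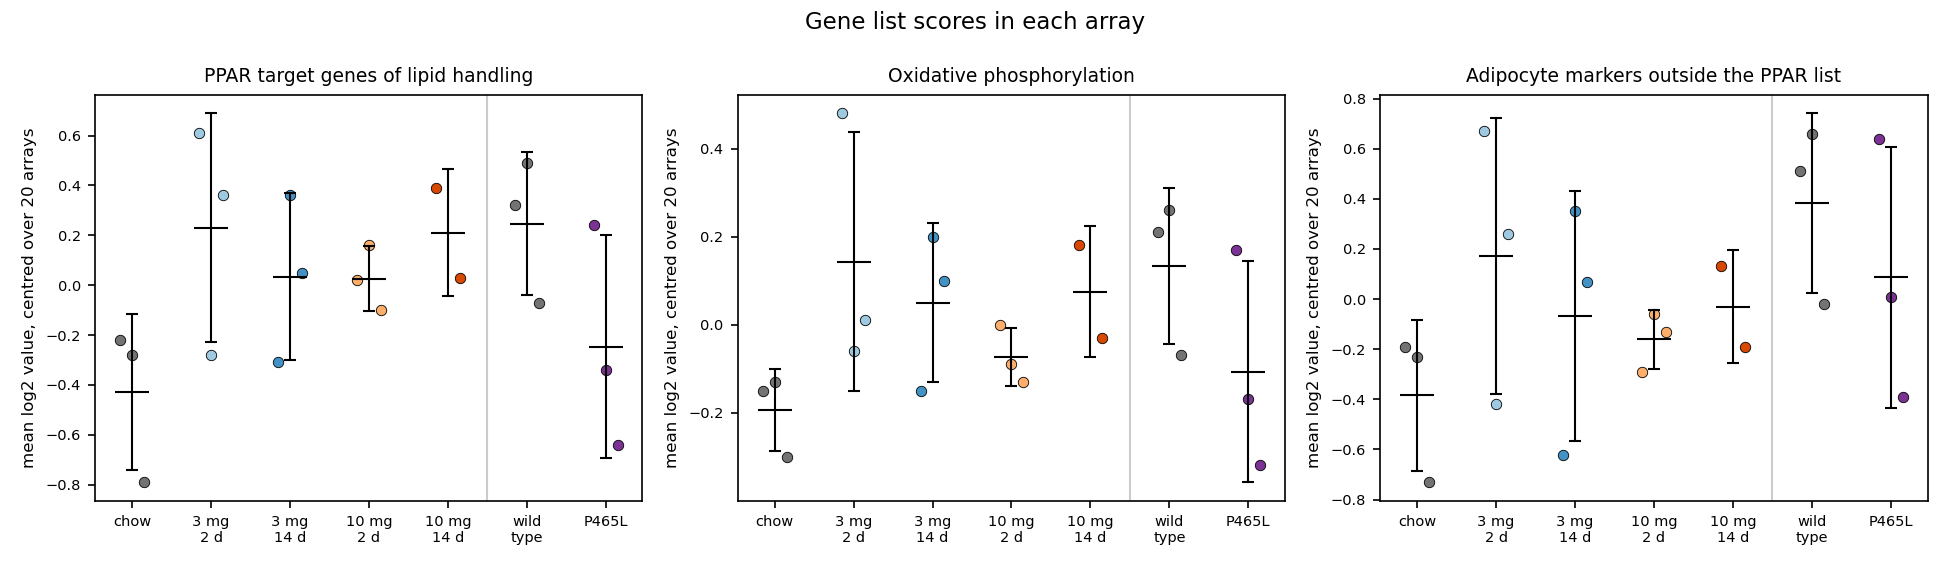
Score of 3 gene lists (y axis, mean log2 value of the members, centred over the 20 arrays) in each array, by group (x axis). Points are arrays, horizontal bars are group means and error bars are 1 SD. Chow controls had PPAR target scores of -0.22, -0.28 and -0.79, and P465L arrays had 0.24, -0.34 and -0.64.

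The labels pair activation with interference, so the log2 fold changes of both experiments were set side by side. No gene was called in opposite directions in both, and Map3k12 was called higher in both. At an unadjusted p under 0.05 in each, a threshold chosen after seeing the data, 68 genes were higher with rosiglitazone on average and lower with P465L, where 23 would be expected of independent lists (two-sided Fisher's exact p = 2.61e-16). Another 32 were lower with rosiglitazone and higher with P465L, where 35.6 would be expected (exact p = 0.592). In the same direction, 26 were higher in both (24.7 expected) and 43 lower in both (33.2 expected). Both comparisons took the variance of a gene from the same fit, so their lists are not independent even without a shared effect. The expected counts, here and with the covariate below, may therefore be too low. Acaa1b (2.00 with rosiglitazone, -1.90 with P465L), Btnl9 (1.43, -1.08) and Fbxo36 (0.78, -0.69) were among the opposite genes, and so were Cyp2f2 (-1.32, 1.5) and Limd2, a LIM domain protein (-0.50, 0.43). Map3k12 (0.74, 1), Pfn1 (-0.56, -0.49) and Flnc (-0.45, -0.42) were among those alike, with the histone demethylase Kdm3b (-0.35, -0.47) and the growth factor signalling inhibitor Spry2 (0.36, 0.50). At 3 mg/kg/day for 2 days 131 genes were opposite and 12 alike by this threshold, at 3 mg/kg/day for 14 days 64 and 43, at 10 mg/kg/day for 2 days 54 and 103, and at 10 mg/kg/day for 14 days 60 and 98. The difference between these groups was not tested. Across all 11081 genes Pearson's r was -0.079 and Spearman's rho 0, and by group r was -0.276 for 3 mg/kg/day at 2 days and 0.05 for 10 mg/kg/day at 14 days. Genes are not independent replicates. With the adipocyte score as a covariate, 42 and 28 genes were opposite where 22 and 31.5 would be expected, 44 were higher in both (22.5 expected) and 54 lower in both (30.8 expected), so that alike genes outnumbered opposite ones. In that fit r was 0.07, and with the stricter filter it was -0.137. Without wild-type array B it was 0.003, so its sign turned. Without chow control A or C it was -0.15 or -0.007, without 3 mg/kg/day 2-day array A it was -0.031, and without P465L array A or C it was -0.133 or -0.025.

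**Figure D3:**
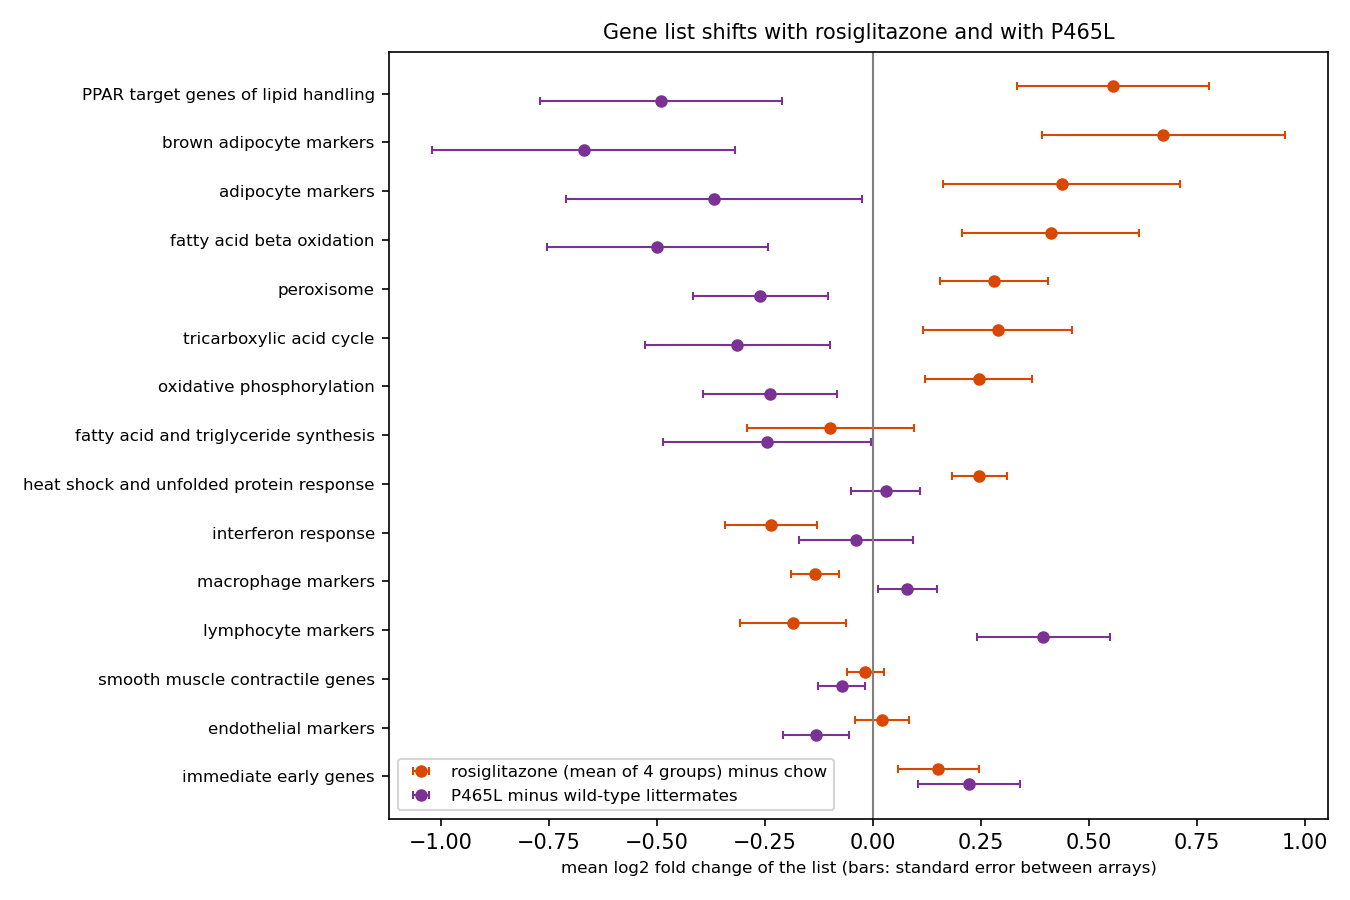
Mean log2 fold change (x axis) of 15 gene lists (y axis) with rosiglitazone on average against chow and with P465L against wild-type littermates. Points are the shifts of the list scores and bars are standard errors between arrays. The PPAR target list had 0.56 ± 0.22 with rosiglitazone and -0.49 ± 0.28 with P465L, and fatty acid and triglyceride synthesis had -0.10 ± 0.19 and -0.24 ± 0.24.

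Chow controls and wild-type littermates, the 2 untreated groups, were also compared, as wild-type littermates minus chow controls. Limma called 719 genes, 288 higher and 431 lower in the littermates, and 2493 genes had an unadjusted p under 0.05. Gdpd3, a lysophospholipase, was 15.59-fold higher and Adcy1, an adenylyl cyclase, 9.13-fold higher (adjusted p = 5.02e-12). Pam, an enzyme of peptide hormone maturation (8.76-fold), Cap1, an actin regulator (6.51-fold), and the heparan sulfate proteoglycan Sdc4 (4.69-fold) were also higher. The small GTPases Rab6b (-3.79) and Rasl10b (-2.29), the ubiquitin ligase Rnf157 (-1.89), the interferon-inducible GTPase Irgm2 (-1.67) and the MHC class II chain H2-Ab1 (-1.58) were lower. Of the genes that were always named, Ucp1 (1.68), Cd36 (1.47), Ppara (1.32), Pdk4 (1.30), Angptl4 (1.29), Fabp4 (0.76) and Cat (0.64) were called, all higher in the littermates. The others of that set that were tested were not called. These genes were taken by the rule for named genes and are not a count over a list. With rosiglitazone on average against the same chow controls Ucp1 had 1.38, Cd36 1.07, Ppara 1.03, Angptl4 1.26 and Cat 0.38, each below the value of the untreated littermates. Pdk4 (1.44) and Fabp4 (0.84) had more with rosiglitazone. The 2 shifts were not tested against each other, and for Angptl4 the standard errors were 0.31 in the littermates and 0.25 with rosiglitazone. The adipocyte score was higher by 0.76 ± 0.33 (SE). Pparg (0.83, adjusted p = 0.209), Lpl (0.90, adjusted p = 0.0802) and Adipoq (0.84, adjusted p = 0.102) did not pass. Of 326 called genes with another probe set, 275 moved the same way there, with a median of 0.5 of the reported log2 fold change. Without chow control A, B or C the count was 441, 417 or 322, and without wild-type array B it was 279. It was 449 with the mean of the probe sets of a gene, 425 at 1.5-fold or more and 473 with the adipocyte score as a covariate.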

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

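The tests of the PPAR target list minus the adipocyte score were chosen only after the result was seen, and the fit with the adipocyte score as a covariate was added after seeing the data. Between the rosiglitazone groups, 9 gene lists differed by dose and 10 by time with the preset correlation, and 0 differed by either with an estimated correlation. Among 3130 probe sets without a single gene name, which the comparisons did not use, 15 changed at 10 mg/kg/day for 2 days (5 higher, 10 lower), 2 at 10 mg/kg/day for 14 days (0 higher, 2 lower) and 13 with rosiglitazone on average (5 higher, 8 lower). At an unadjusted p under 0.05 these comparisons had 360, 262 and 305 such probe sets. Of 82 called genes, 0 moved in opposite directions in every array of 2 rosiglitazone groups. Single arrays far from their group could not be sought by a rule for outliers, since every group held 2 or 3 arrays.

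PPAR target genes and genes of oxidative phosphorylation stood higher with rosiglitazone by camera with the preset correlation, by 0.56 ± 0.22 (SE) and 0.25 ± 0.12 (SE) on the log2 scale, and neither passed with an estimated correlation (adjusted p = 0.442 for each). The scaling of the arrays was argued against, since after quantile normalization the shift of the PPAR target list was 0.55 ± 0.22 (SE). For oxidative phosphorylation the shift with the adipocyte score as a covariate was 0.09 ± 0.06 (SE), as a different share of fat in the pools would give. That share stays a hypothesis, since a change within fat cells that moved the score would shrink this shift too. Of the 24 adipocyte markers 20 lay above the filter. Chow controls already had an Adipoq signal of 27910 ± 8450 (SD, n = 3) and a Fabp4 signal of 67410 ± 17300 (SD, n = 3). For the PPAR target list, the list minus the score moved by 0.2 ± 0.07 (SE), and its shift with the covariate was 0.26 ± 0.06 (SE), yet a different share of fat and a change of these genes within cells cannot be told apart, because the score holds Pparg and 4 genes of fatty acid and triglyceride synthesis (Thrsp, Agpat2, Dgat2 and Pnpla3), which PPARγ activation may move by itself. Activation of PPARγ, the difference that the design names, stays open, and so do chow controls that were low by themselves, since untreated wild-type littermates stood above the same 3 controls by 0.68 ± 0.28 (SE) on the PPAR target list.

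The same lists had lower means with P465L by camera with the preset correlation, at -0.49 ± 0.28 (SE) for PPAR target genes and -0.24 ± 0.16 (SE) for oxidative phosphorylation, both under 2 standard errors between arrays, and neither passed with an estimated correlation (adjusted p = 0.389 for each). After quantile normalization the PPAR target shift was -0.46 ± 0.27 (SE), which argued against the scaling of the arrays. With the adipocyte score as a covariate the shift of oxidative phosphorylation was -0.11 ± 0.07 (SE), as a smaller share of fat in the P465L pools would give. That share stays a hypothesis from the same 24 markers, since a change within fat cells that moved the score would shrink this shift too. The Adipoq signal was 38040 ± 14900 (SD, n = 3) in P465L arrays and 49460 ± 12800 (SD, n = 3) in wild-type littermates. Retn and Pparg, the other always named members of the score, were not lower. Their signals were 4412 ± 1940 against 3682 ± 718 and 2169 ± 1110 against 2132 ± 553 (SD, n = 3). The PPAR target list minus the score moved by -0.19 ± 0.09 (SE), and its shift with the covariate was -0.25 ± 0.07 (SE), but fat share and a change within cells cannot be told apart, since the score holds Pparg and genes that PPARγ may regulate. Interference with PPARγ stays open as the design's own difference.

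Many genes, 719, differed between wild-type littermates and chow controls, although both groups were untreated. A different share of fat in the pools was argued against as the whole cause, since 473 genes were called with the adipocyte score as a covariate, 318 of them among the 719. With that covariate the PPAR target list shifted by 0.05 ± 0.08 (SE) in place of 0.68 ± 0.28 (SE), so for this list a difference in fat may account for its shift. Sequence variants under single probe sets, such as those between mouse strains, cannot be told apart from changes of transcript level, because 84.4% of called genes with another probe set moved the same way there, between the 75 and 90% set as bounds, and the labels give no strain for the littermates. Strain background, cohort and array run were not tested, as each coincides with the 2 groups. The ratio of 3' to 5' signal of Gapdh was 0.90, 0.96 and 0.90 in chow controls and 0.83, 0.80 and 0.82 in wild-type littermates, while that of Actb overlapped. Whether RNA quality had a part in the 719 calls was not tested.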

How the results depend on the processing

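The fit with the adipocyte score as a covariate and the leaving out of arrays in the list tests and list means were chosen after the results were seen. The direction of all called genes, and not only the named ones, was also followed after the results were seen. With the mean of the probe sets of a gene, Ifngr2 turned to 0.14 on average and 0.12 at 10 mg/kg/day for 2 days, Axl turned to 0.11 and 0.18, and Map3k12 turned to -0.02 on average, none of them called there. Of the 719 genes between the untreated groups 22 turned with that setting, with Xaf1 called at 1.29 in place of -0.71, and 1 turned with quantile normalization. No other called gene that an alternative kept turned its direction. The r between rosiglitazone and P465L changed sign with the covariate and without wild-type array B. The cause was not tested for any change below, except that the fold threshold and the stricter filter remove genes by construction and that fewer arrays leave fewer degrees of freedom.

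With quantile normalization, P465L had 1 called gene in place of 2 and 2 lists differed by dose in place of 9. With no filter, 0 genes were called at 10 mg/kg/day for 14 days in place of 30, and 0 were shared between the rosiglitazone groups in place of 16. With the stricter filter P465L had 1, and r between rosiglitazone and P465L was -0.137 in place of -0.079. With the mean of the probe sets of a gene, 27 genes were called at 10 mg/kg/day for 2 days in place of 56 (17 of them shared), 1 with P465L, 449 between the untreated groups in place of 719, and 7 overlapped. With only the arrays of the experiment the counts were 14 at 10 mg/kg/day for 2 days, 9 at 14 days, 0 with P465L, 5 for time in place of 0, and 6 for the overlap. Without the variance trend they were 13, 0, 28 for the average of 48, 1 with P465L and 0 for the overlap. With array weights, which ranged from 0.39 for 3 mg/kg/day 2-day array A to 2.66 for P465L array B, they were 612, 256, 260, 6 and 147. At 1.5-fold or more they were 25 for the average and 425 between the untreated groups. The replicate letter as a block gave 1 for P465L in place of 2 and 2 for dose in place of 0, and ended 7 of 21 named calls at 10 mg/kg/day for 14 days and 2 of 26 at 2 days. With the adipocyte score as a covariate the counts were 12 at 3 mg/kg/day for 14 days in place of 0, 224 and 122 at 10 mg/kg/day for 2 and 14 days, 125 for the average, 7 with P465L, 11 for dose, 2 for time, 473 between the untreated groups and 73 for the overlap. The r was 0.07. All 56, 30, 48 and 2 genes called without the covariate stayed called at 10 mg/kg/day for 2 days, at 14 days, on average and with P465L.

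With an estimated correlation, 0 lists passed in place of 14 and 12 at 3 mg/kg/day, 12 and 17 at 10 mg/kg/day, 11 on average, 18 with P465L, 9 for dose and 10 for time. With fry, 1 list passed at 10 mg/kg/day for 14 days and 0 in each other comparison. With the covariate and an estimated correlation 0 passed in each, and with the covariate and the preset correlation 17 passed on average.

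Without single arrays the count of called genes ranged from 0 to 3 and from 0 to 5 at 3 mg/kg/day for 2 and 14 days, from 0 to 18 and from 0 to 9 at 10 mg/kg/day, from 1 to 83 on average, from 0 to 3 with P465L and from 279 to 620 between the untreated groups. It stayed 0 for dose, time and the interaction. The overlap ranged from 0 to 25 and r from -0.15 to 0.003. Lists ranged from 14 to 16 and from 11 to 14 at 3 mg/kg/day, from 10 to 12 and from 13 to 17 at 10 mg/kg/day, from 11 to 14 on average, from 16 to 17 with P465L, from 7 to 16 for dose and from 9 to 15 for time. Where 1 array was left at 10 mg/kg/day for 14 days, it was assumed to vary like the other groups. For the named genes, leaving out an array ended a call 355 times, made one 7 times, and left the side of the threshold 1085 times. Dropping the variance trend ended 52 calls, no filter 41, a fit to only the arrays of the experiment 40 and the mean of the probe sets 31, while the covariate made 17 and array weights 13. With P465L, the call of Map3k12 ended in 5 of 6 arrays left out and that of Elovl3 in 4 of 6.

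The fold threshold does not apply to r, and a fit with only the arrays of the experiment does not apply to the untreated groups, which belong to different experiments. Both were not run. MAS5 signal near the background limits what dim genes can show: genes with a mean signal under 352 were not tested, and the median standard error of a log2 fold change was 0.154 for 3 arrays against 3.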

Other observations

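The leaving out of arrays from the lists below was chosen after seeing the data. The tests of liver markers were chosen only after the values of albumin were seen, and the second of them after the result of the first.

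Genes of tissues that border the aorta varied between arrays. The skeletal muscle score, which includes fast-muscle genes of contraction, averaged 1.24 ± 0.91 (SD, n = 3) in wild-type littermates, with a highest array of 2.26, and -1.09 ± 0.33 (SD, n = 2) at 10 mg/kg/day for 14 days. By time, 16 of 18 skeletal muscle markers were lower at 14 days (mean -0.70, adjusted p = 5.17e-05 by camera from limma, and adjusted p = 0.632 with an estimated correlation), with a mean of -0.47 without 10 mg/kg/day 2-day array B. Cardiac muscle markers were higher at 14 days in 10 of 11 members (mean 0.28, adjusted p = 0.00204, and adjusted p = 0.303 with an estimated correlation), but without 10 mg/kg/day 14-day array A they did not pass (mean 0.09, adjusted p = 0.278), and without array B the mean was 0.47. The red blood cell score reached 1.78 in wild-type array B, where the group averaged 0.72 ± 0.93 (SD, n = 3), and was lowest at 10 mg/kg/day for 14 days, at -0.84 ± 0.23 (SD, n = 2). None of these 3 lists had a member called over all genes by limma in any of these comparisons.

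Lists of vessel wall matrix genes passed camera with the preset correlation and not with an estimated one. Collagens and collagen processing were higher at 3 mg/kg/day for 2 days in 22 of 28 members (mean 0.11, adjusted p = 8.52e-05 by camera, and adjusted p = 0.26 with an estimated correlation). They were lower at 14 than at 2 days in 23 of 28 (mean -0.08, adjusted p = 3.82e-05, and adjusted p = 0.407 with an estimated correlation) and lower at 10 than at 3 mg/kg/day in 23 of 28 (mean -0.09, adjusted p = 0.00237, and adjusted p = 0.667 with an estimated correlation). Fibroblast and adventitial markers were lower at 14 days in 20 of 23 (mean -0.10, adjusted p = 3.64e-05, and adjusted p = 0.456 with an estimated correlation). Without 10 mg/kg/day 14-day array A the collagen means were -0.06 by dose and -0.05 by time, and without 10 mg/kg/day 2-day array A that by time was -0.05, and that of fibroblast markers was -0.07 without 3 mg/kg/day 14-day array B. By limma 0 members of these lists were called over all genes for dose or time.

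Other splits of the same arrays into groups of the same sizes were fitted in the same way. For rosiglitazone on average, 3 of 100 splits, the real one included, called as many as the 48 genes, a share under 0.05. The highest other split called 378 and another 134, several times the real count, so a regrouping of these arrays can call more genes than the real groups. The cause of these counts was not identified. For dose the real count was 0, so 100 of 100 splits called as many, and the highest other called 244, a count whose cause was not identified either. For time the real count was 0, 100 of 100 splits called as many, and the highest other called 23. The comparisons of 3 arrays with 3 had only 10 splits, too few for a share under 0.05. At 10 mg/kg/day for 2 days 1 split, the real one, called 56 and the highest other 0, and between the untreated groups 1, the real one, called 719 and the highest other 0. With P465L 3 splits called as many as the real 2, with 2 the highest other, and at 3 mg/kg/day 10 of 10 splits called as many as the real 0, with 0 the highest other, at each time.

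One hypothesis was that genes linked to the targeted Pparg locus on chromosome 6 differ between P465L mice and littermates because the targeted chromosome segment may carry variants of another strain. Among the 100 tested genes nearest to Pparg, 5 had an unadjusted p under 0.05, a share of 5% against 7.45% of the other 10981 genes, a ratio of 0.67 (Fisher's exact p = 0.445). The bound set for the hypothesis was a ratio above 2, so linked genes were argued against as a main part of the difference. A few linked genes, or a segment shorter than this window, might not raise the share and are not excluded.

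Another hypothesis, from the lower albumin signal in P465L arrays, was that the wild-type pools may have held some liver, from a list of 25 liver markers. Alb had log2 values of 9.54, 12.11 and 11.32 in wild-type arrays and 8.66, 6.63 and 7.32 in P465L arrays, and Apoa2 had a log2 fold change of -1.77. Alb also varied in the other experiment, at 8.13, 9.89 and 10.54 in chow controls, 6.96, 6.57 and 8.07 at 3 mg/kg/day for 2 days, and 8.54, 9.37 and 10.39 at 10 mg/kg/day for 2 days, so a varying signal was not particular to the wild-type pools. Among the 5 other liver markers above the filter the median was -0.24, with 3 lower. This value excludes nothing, since only 7 of the 25 markers lay above the filter, among them Alb and Apoa2 themselves and Itih4 at 14.28, 14.01 and 13.90 in wild-type arrays, and whether the aorta expresses these 7 was not tested. Without the filter the median of 23 other markers was -0.87, with 20 lower, and at an unadjusted p under 0.05 by limma 11 were lower and 0 higher. The largest of these were Apoa1 (-2.67), Fga (-2.14) and Fabp1 (-2.08). Fga had an unadjusted p of 1.99e-06 by limma without the filter, small enough to pass the adjusted threshold over the 18193 genes of that fit. Liver in the pools and lower expression of these genes in the aorta cannot be told apart, because the median lay between the bounds set for the test and most of the 23 markers lay below the level required for testing. The offset also limits how far dim markers can fall, which draws the median toward 0. Fgb, for example, was at 6.46 and 6.34 in wild-type arrays A and B and at 6.37, 6.24 and 6.27 in P465L arrays.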
